A study of Phaeobacter inhibens DSM 17395 with 24 samples.

How the data were processed

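The series holds 24 RNA sequencing libraries of *P. inhibens* DSM 17395 in 8 groups of 3, from 3 independent cultures per the design text. Per the labels' protocols, RNA was extracted with the RNeasy kit after lysozyme and glass beads, digested with DNase I in 2 steps, depleted of ribosomal RNA with Ribo-Zero, and made into strand-specific single-end libraries with ScriptSeq v2. Sequencing was on a HiSeq 2500 with 50 bp reads, per the labels. Library names place untreated, DMSO, DMSP and C18:1 in lane 3 and 3OH-C10, C14:1, TDA and eDNA in lane 4, while the protocol speaks of a single lane. By the names, only 4 of the 10 comparisons lie within a lane: DMSO and untreated, C18:1 and DMSO, DMSP and untreated, and 3OH-C10 and C14:1.

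Per the submitters' processing notes, reads were mapped with Bowtie2 and handled with SAMtools, whose versions they do not give. The deposited counts are raw counts of reads per coding sequence from featureCounts 1.4.6-p3, per the file headers. The headers also record stranded assignment, with reads that overlap several features and reads with several alignments counted for each of them. Reads on identical gene copies such as the tuf genes therefore count for each copy, and an overlap with a neighbour on the same strand counts for both genes. Of 117 genes named in the report, 30 overlap such a neighbour, by at most 8 bp (4.68% of the coding sequence). Only coding sequences were counted, so shares of ribosomal and transfer RNA were not analysed here, and 0 per-sample columns were left unused.

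Each file lists 3920 coding sequences. Their coordinates were matched to a reference gene table by both ends (3602) or by the stop codon end alone (259), and 59 did not match. A symbol was found for 796, of which 795 were tested. Genes were kept with filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total 15, large-sample size 10, proportion 0.7), which left 3865. Counts were scaled with TMM factors, which ranged from 0.708 to 0.978 for untreated, 3OH-C10 and eDNA libraries and from 1.02 to 1.24 for the other groups. All 8 groups were fitted in 1 model by group, without a replicate block, with 16 residual degrees of freedom, using the robust quasi-likelihood method of edgeR, and each comparison was a contrast. The threshold was an adjusted p under 0.05 by the Benjamini-Hochberg method. Standard errors are the log2 fold change divided by the square root of F. R 4.3.3, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used.

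Libraries held 5996270 to 10445890 counts. Median coefficients of variation within a group ran from 5% (TDA) to 13.7% (untreated) and 13.6% (eDNA). The 24 replicate pairs differed beyond counting noise, with chi-square per degree of freedom from 5.38 (3OH-C10) to 134 (eDNA). Simulations had 3865 genes, 50 changed per fold. Tests recovered 86 to 98% of 2-fold changes, 57.1 to 78% of 1.5-fold and 6 to 26% of 1.25-fold. Of the calls 1.56 to 6.71% were false. A 12-member list planted at 1.5-fold was called 20 of 20 times, and 0 of 300 unchanged lists were. Lists of correlated genes were not checked.

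Gene lists were tested with camera at its preset correlation of 0.01, for lists with at least 5 tested members. They came from patterns on gene symbols and replicons. Of the fixed lists 15 were tested, and 13 more were chosen after the symbols were read and before any count was tested. The 12 lists resting on product names had no members, since genes were grouped by symbol. The alternatives were a correlation estimated per list and the rotation test fry. Runs, chosen after the data were seen, hold at least 4 neighbouring genes on 1 strand, at most 300 bp apart. All were called and changed at least 2-fold the same way.

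Genes named as changed follow a rule written partly before the data were examined. Genes named as not passing mostly lie outside it. Among genes past the threshold whose groups do not overlap, the 10 largest rises and 10 largest falls were eligible (5 between AHLs), taken over all genes and again over genes with a symbol. Up to 3 members per fixed list with the smallest p were added, at most 3 genes without a symbol were named per comparison beside runs, and DMSP genes, dprA, comD and comE were named whatever their p. The competence list matched comD and comE by symbol, but these also denote sulfopyruvate decarboxylase subunits, so only dprA is called a competence gene. Alternatives were DESeq2, its size factors within edgeR, no filter, a fit of the 2 groups alone, a replicate block, the other control, each library left out in turn, and total-count scaling, the last added after the TMM factors were seen. For the overlap, all 15 libraries were simulated from mean DMSO levels, DMSO libraries included.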

Results

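Cultures of *Phaeobacter inhibens* DSM 17395, a marine bacterium of the Rhodobacteraceae, were grown in chemotaxis medium and sequenced as 24 RNA libraries in 8 groups of 3 (n = 3 libraries per group throughout). Cells were left untreated or received the solvent dimethyl sulfoxide (DMSO, 14 mM), one of 3 acyl-homoserine lactones (AHLs, fatty-acyl signal molecules of bacteria, each at 1 µM), tropodithietic acid (TDA, an antibiotic made by this genus, 10 µM), dimethylsulfoniopropionate (DMSP, a sulfur compound of marine algae, 500 µM) or extracellular DNA (eDNA, 5 µg/ml). The AHLs are called 3OH-C10, C14:1 and C18:1 after their acyl chains. Reads of 50 bp had been assigned to 3920 coding sequences on the chromosome (3568) and on the plasmids pPGA1_262 (240), pPGA1_78 (63) and pPGA1_65 (49). Libraries held from 5996270 counts (DMSO replicate C) to 10445890 (untreated replicate C), and 3865 genes were tested. All 24 libraries lay closest to a library of their own group, and the first 2 principal components held 57.9% and 20.4% of the variance. In what follows, log2 fold changes are given ± standard error, adjusted p values come from edgeR quasi-likelihood tests with the Benjamini-Hochberg method, and expression is in CPM, counts scaled to library size with TMM factors. AHLs and TDA were compared with DMSO, and DMSP and eDNA with untreated cells, a choice made before the data were examined, since the labels do not say which control belongs to which substance.

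**Figure D1:**
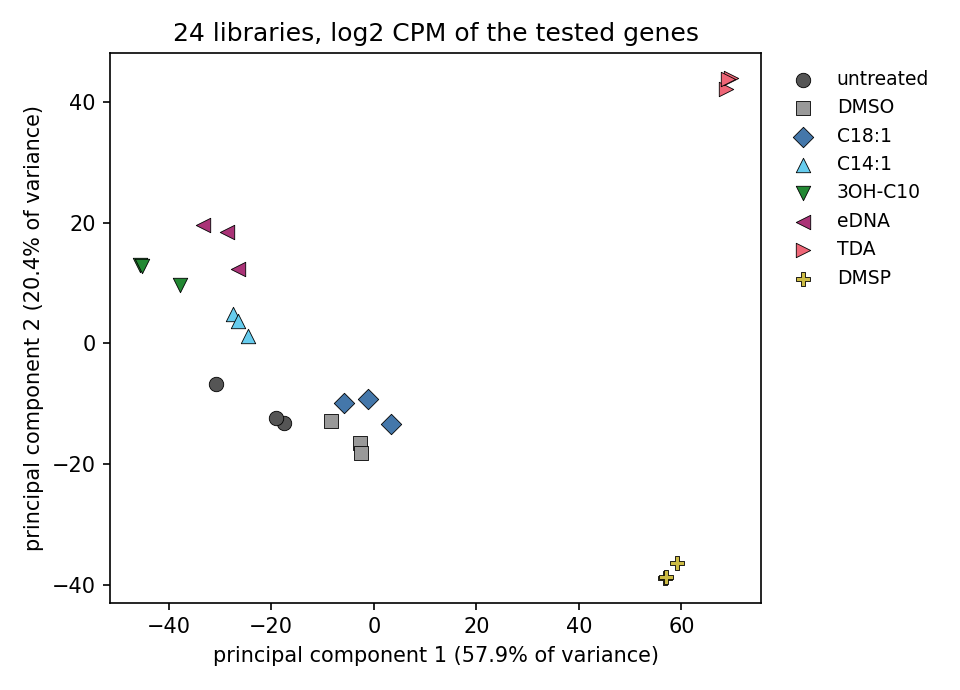
Principal components of the 24 libraries from log2 CPM of the 3865 tested genes. Each symbol is 1 library, and 3 libraries share each colour. Component 1 holds 57.9% and component 2 holds 20.4% of the variance.

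The solvent alone lowered flagellar genes, recA, dprA and a 21-gene run on the chromosome, and raised ribosomal protein genes. All 12 tested flagellar genes fell with DMSO, among them fliE (-1.17 ± 0.14, adjusted p = 1.33e-06, 176 against 398 CPM), motA, a stator gene of the flagellar motor (-1.16 ± 0.16, adjusted p = 1.08e-05, 1200 against 2670 CPM), and flhA, of the flagellar export gate (-1.18 ± 0.15, adjusted p = 3.44e-06, 1270 against 2870 CPM). The recombinase gene recA (chromosome 1589307–1590374) fell (-1.43 ± 0.20, adjusted p = 1.19e-05, 1040 against 2800 CPM), as did dprA, whose product loads RecA onto incoming DNA (-1.64 ± 0.35, adjusted p = 0.000913, 8000 against 24900 CPM). Untreated libraries differed widely for dprA (8000 ± 776 against 24900 ± 16300 CPM (mean ± SD)), and its log2 fold change was -0.98 (adjusted p = 0.0113) without untreated replicate C. The largest falls lay in a run of adjacent genes without symbols, PGA1_c13630 to PGA1_c13830 (chromosome 1408175–1430131, between chrA and acuI; 21 genes, median log2 fold change -3.83, median 129 against 1.32e+03 CPM), with PGA1_c13770 lowest (-4.15 ± 0.27, adjusted p = 4.36e-10, 187 against 3320 CPM).

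Other falls with DMSO included preA, for a subunit of dihydropyrimidine dehydrogenase (-2.28 ± 0.21, adjusted p = 4.35e-08, 947 against 4590 CPM), hydA (-1.46 ± 0.15, adjusted p = 2.34e-07, 832 against 2300 CPM) and the nitrite reductase gene nirK (-1.41 ± 0.40, adjusted p = 0.00816, 131 against 349 CPM). The catalase gene katG (-1.10 ± 0.14, adjusted p = 6.02e-06, 416 against 890 CPM) fell, as did ctrA, the cell-cycle regulator that also governs flagellar genes in this family (-0.91 ± 0.14, adjusted p = 4.84e-05, 6440 against 12100 CPM). The division gene ftsA (-0.96 ± 0.12, adjusted p = 4.52e-06, 651 against 1260 CPM) and the protease gene clpA (-0.85 ± 0.14, adjusted p = 6.68e-05, 2200 against 3970 CPM) fell too. Among the rises were ilvC, of branched-chain amino acid synthesis (1.34 ± 0.15, adjusted p = 6.27e-07, 380 against 150 CPM), the chaperonin gene groL (1.31 ± 0.14, adjusted p = 3.73e-07, 4960 against 2000 CPM), the transketolase gene tkt (1.11 ± 0.16, adjusted p = 1.46e-05, 47.5 against 22.1 CPM) and a formate dehydrogenase gene, fdhF (1.10 ± 0.21, adjusted p = 0.000278, 913 against 425 CPM). A run on pPGA1_78, PGA1_78p00160 to PGA1_78p00210 (19046–25194), rose as well (6 genes, median log2 fold change 1.59, median 108 against 36.6 CPM), led by PGA1_78p00160 (1.84 ± 0.12, adjusted p = 4.36e-10, 696 against 195 CPM). Genes for ribosomal proteins rose, such as rplR (1.02 ± 0.16, adjusted p = 3.16e-05, 351 against 173 CPM) and rplS (0.76 ± 0.11, adjusted p = 2.06e-05, 243 against 144 CPM), and so did atpD and atpA of ATP synthase (0.92 ± 0.15, adjusted p = 6.6e-05, 1010 against 536 CPM and 0.93 ± 0.17, adjusted p = 0.000237, 406 against 214 CPM).

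By lists fixed before the data were examined, of 50 ribosomal protein genes 45 rose, 0 fell and 5 did not pass (47 and 0 adjusted over the list alone, median log2 fold change 0.73). By camera, ribosomal protein genes had adjusted p = 1.35e-11, and adjusted p = 0.437 with an estimated correlation. Among 12 flagellar genes 0 rose, 12 fell and 0 did not pass (0 and 12 adjusted over the list alone, median log2 fold change -1.06). Camera gave flagellar genes adjusted p = 6.14e-11, and adjusted p = 0.437 with an estimated correlation. Of 22 genes for ATP synthase and the respiratory chain, 13 rose, 2 fell and 7 did not pass (13 and 2 adjusted over the list alone, median log2 fold change 0.42). For respiratory genes camera gave adjusted p = 0.034, and adjusted p = 0.597 with an estimated correlation. Among 240 genes of pPGA1_262, 7 rose, 63 fell and 170 did not pass (7 and 59 adjusted over the list alone, median log2 fold change -0.13 (0.17 under total counts)). pPGA1_262 genes had a camera adjusted p = 0.00384, and adjusted p = 0.437 with an estimated correlation. These 4 of 15 lists passed camera with its preset correlation, and 0 passed with a correlation estimated per list, where 1 had an unadjusted p under 0.05 and the rotation test fry called 8. In all, 1697 genes changed with DMSO, 925 higher and 772 lower, and 194 of them at least 2-fold (35 up, 159 down). The fit of the 2 groups alone gave 1120 genes, 532 higher and 588 lower, and without untreated replicate B the split was 810 and 831. With total counts in place of TMM factors the split was 1856 higher and 375 lower, with an all-gene median of 0.318 in place of 0.02. The 3 libraries of one group all lay outside those of the other for 48.4% of genes, against 10% expected by chance.

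**Figure D2:**
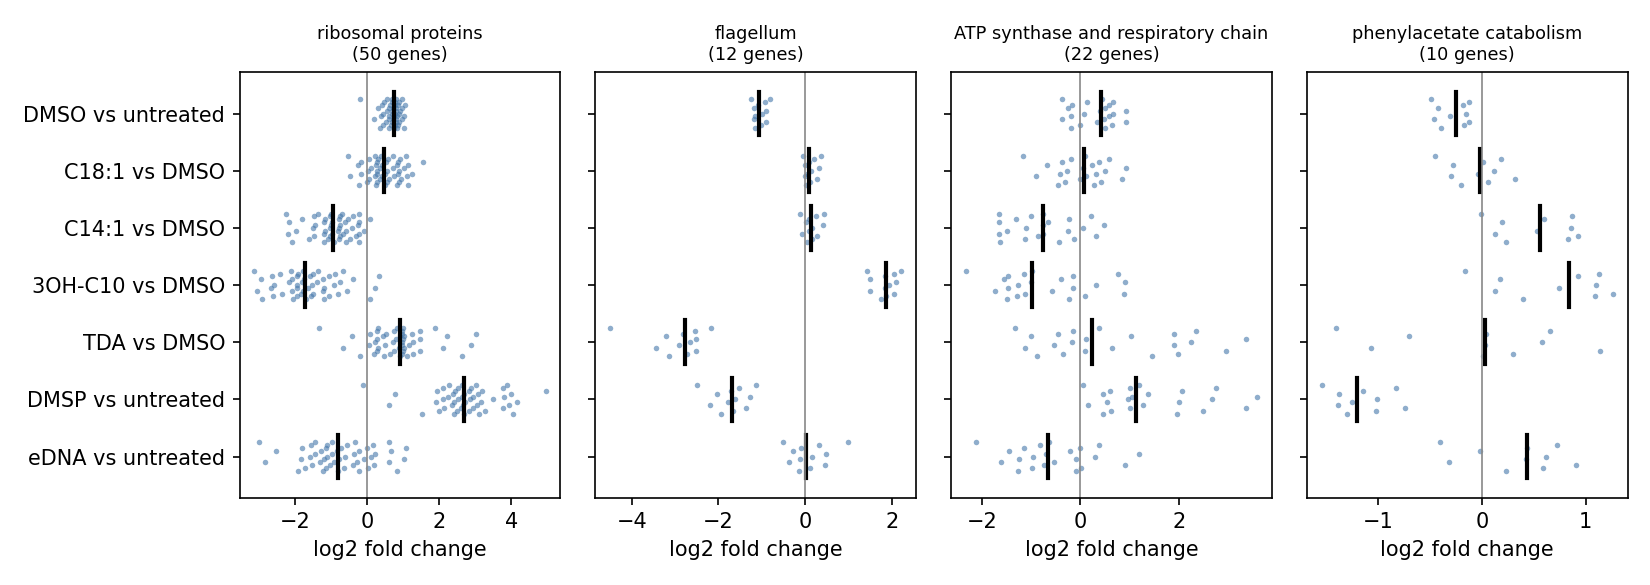
Log2 fold changes of the genes of 4 lists in the 7 comparisons of a treatment with its control, n = 3 libraries per group. Each point is 1 gene and the black bar is the list median. Medians of ribosomal protein genes run from -1.73 (3OH-C10) to 2.68 (DMSP). For phenylacetate genes the median of -0.25 with DMSO became 0.05 under total counts, and the C18:1 median was -0.01 (-0.08 to 0.07 without 1 library). The flagellar median with eDNA was 0.01 (-0.17 to 0.19 without 1 library).

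The AHL 3OH-C10 raised flagellar genes, recA, dprA, rocF, hppD and hutG and lowered ribosomal protein genes, glnA and gltB. The arginase gene rocF (chromosome 1697971–1698897) rose (3.54 ± 0.14, adjusted p = 1.49e-14, 171 against 14.7 CPM), together with the ornithine cyclodeaminase gene ocd (3.04 ± 0.15, adjusted p = 3.71e-13, 330 against 40.3 CPM) and ctlX (2.89 ± 0.12, adjusted p = 3.46e-14, 220 against 29.7 CPM). Rises followed in hppD, of tyrosine breakdown (chromosome 786673–787773, 3.47 ± 0.22, adjusted p = 2.85e-11, 533 against 48.2 CPM), and in the histidine utilization genes hutG (2.75 ± 0.19, adjusted p = 3.5e-11, 64.7 against 9.63 CPM), hutH (2.63 ± 0.17, adjusted p = 2.71e-11, 140 against 22.6 CPM) and hutU (2.15 ± 0.14, adjusted p = 2.03e-11, 93.7 against 20.9 CPM). Glutamine synthetase glnA (chromosome 1941967–1943373) showed the largest fall among genes with a symbol (-3.83 ± 0.43, adjusted p = 2.01e-07, 98.5 against 1400 CPM), and the glutamate synthase gene gltB fell as well (-2.69 ± 0.20, adjusted p = 1.49e-10, 185 against 1200 CPM).

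Flagellar genes rose with 3OH-C10: flgN, a flagellar chaperone gene (2.22 ± 0.19, adjusted p = 7.17e-10, 3990 against 858 CPM), motA (2.09 ± 0.16, adjusted p = 2.5e-10, 5110 against 1200 CPM), fliE (2.05 ± 0.14, adjusted p = 3.53e-11, 730 against 176 CPM) and flhA (1.86 ± 0.15, adjusted p = 3.55e-10, 4620 against 1270 CPM). The genes ctrA (1.46 ± 0.14, adjusted p = 8.33e-09, 17700 against 6440 CPM), sciP, a partner of CtrA (1.82 ± 0.17, adjusted p = 4.25e-09, 1940 against 550 CPM), and ftsA (1.57 ± 0.12, adjusted p = 2.92e-10, 1930 against 651 CPM) rose too. Both recA (2.30 ± 0.20, adjusted p = 1.43e-09, 5140 against 1040 CPM) and dprA (2.19 ± 0.36, adjusted p = 1.64e-05, 36600 against 8000 CPM) rose, but dprA did not pass with untreated cells as control (0.55, adjusted p = 0.198). The stringent-response regulator gene dksA rose (2.21 ± 0.21, adjusted p = 9.95e-09, 418 against 90.5 CPM). Among ribosomal protein genes, rpsE (-3.08 ± 0.18, adjusted p = 3.42e-12, 132 against 1120 CPM), rplQ (-2.94 ± 0.20, adjusted p = 4.43e-11, 59.1 against 455 CPM) and rpmD (-3.14 ± 0.24, adjusted p = 3.55e-10, 11.4 against 101 CPM) fell. Falls were also seen in ilvC (-3.26 ± 0.16, adjusted p = 5.53e-13, 39.7 against 380 CPM), ndk, for nucleoside diphosphate kinase (-3.12 ± 0.19, adjusted p = 1.01e-11, 29.8 against 261 CPM), and groL (-2.83 ± 0.15, adjusted p = 8.69e-13, 696 against 4960 CPM). Falls in energy metabolism covered atpD (-2.33 ± 0.16, adjusted p = 3.35e-11, 202 against 1010 CPM) and nuoL of complex I (-1.74 ± 0.12, adjusted p = 6.62e-11, 413 against 1370 CPM). Of the luxI and luxR families none was named by a symbol, and the quorum sensing list was not analysed here.

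Runs of genes without symbols changed as well. PGA1_c12620 to PGA1_c12670 (chromosome 1307580–1313575, between accB and preA) fell with 3OH-C10 (6 genes, median log2 fold change -5.06, median 28.7 against 971 CPM), with PGA1_c12640 at -5.83 ± 0.29, adjusted p = 8.69e-13, 35.3 against 2010 CPM. An 18-gene run, PGA1_c17700 to PGA1_c17870 (chromosome 1853155–1868021, between cysE and mltG), rose (18 genes, median log2 fold change 2.54, median 57.5 against 8.32 CPM). Of the single genes without a symbol, PGA1_c04490 rose most (4.78 ± 0.22, adjusted p = 3.71e-13, 833 against 30.4 CPM).

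Of 12 flagellar genes, 12 rose, 0 fell and 0 did not pass (12 and 0 adjusted over the list alone, median log2 fold change 1.86). By camera, flagellar genes had adjusted p = 2.47e-09, and adjusted p = 0.362 with an estimated correlation. Among 50 ribosomal protein genes 1 rose, 47 fell and 2 did not pass (1 and 47 adjusted over the list alone, median log2 fold change -1.73). Camera gave ribosomal protein genes adjusted p = 1.62e-17, and adjusted p = 0.362 with an estimated correlation. Of 10 phenylacetate catabolism genes 7 rose, 0 fell and 3 did not pass (7 and 0 adjusted over the list alone, median log2 fold change 0.84 (0.27 under total counts)), with paaA at 1.26 ± 0.10, adjusted p = 3.63e-10, 321 against 134 CPM. For phenylacetate genes camera gave adjusted p = 0.0103, and adjusted p = 0.362 with an estimated correlation. Among 22 ATP synthase and respiratory genes 4 rose, 14 fell and 4 did not pass (4 and 15 adjusted over the list alone, median log2 fold change -0.99). Respiratory genes had a camera adjusted p = 0.00119, and adjusted p = 0.362 with an estimated correlation. Of 240 genes of pPGA1_262 121 rose, 39 fell and 80 did not pass (121 and 39 adjusted over the list alone, median log2 fold change 0.36 (-0.2 under total counts)). By camera, pPGA1_262 genes had adjusted p = 0.00119, and adjusted p = 0.362 with an estimated correlation. Camera called these 5 of 15 lists with the preset correlation and 0 with an estimated one, where 1 had an unadjusted p under 0.05 and fry called 12. Among 9 cell-cycle genes 6 rose, 3 fell and 0 did not pass (6 and 3 adjusted over the list alone, median log2 fold change 0.64 (0.07 under total counts)). Camera gave cell-cycle genes adjusted p = 0.155. Over untreated cells the flagellar median was 0.85 and the ribosomal median -0.98. Altogether 2647 genes changed, 1303 higher and 1344 lower, with 491 up and 407 down at least 2-fold. The balance turned without 3OH-C10 replicate A (1242 higher, 1232 lower) or B (1252 and 1235). Scaling by total counts gave 568 higher and 2313 lower, with an all-gene median of -0.546 in place of 0.014. Groups were fully separated for 73.4% of genes against 10% by chance.

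With C14:1, ribosomal protein genes, glnA and gltB fell over DMSO too, and 5 plasmid genes rose strongly. PGA1_65p00020 to PGA1_65p00060 (pPGA1_65 1376–9465) rose (5 genes, median log2 fold change 5.86, median 904 against 16.8 CPM), with PGA1_65p00040 at 6.33 ± 0.59, adjusted p = 6.99e-08, 5090 against 63.3 CPM. A chromosomal run with comD, comE and a gene with the symbol hisD, hisD PGA1_c07750, rose as well (chromosome 798556–806465), with hisD PGA1_c07750 at 3.21 ± 0.24, adjusted p = 9.83e-10, 109 against 11.9 CPM. The heat-shock sigma factor gene rpoH rose with a wide error (2.50 ± 0.58, adjusted p = 0.00131, 4990 against 883 CPM), as did cpaB, of pilus assembly (1.67 ± 0.18, adjusted p = 9.27e-08, 1630 against 511 CPM). Among genes with a symbol, falls were largest in glnA (-3.51 ± 0.42, adjusted p = 1.13e-06, 123 against 1400 CPM), ilvC (-2.95 ± 0.16, adjusted p = 2.54e-12, 49.3 against 380 CPM) and gltB (-2.92 ± 0.20, adjusted p = 1.18e-10, 157 against 1200 CPM).

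**Figure D3:**
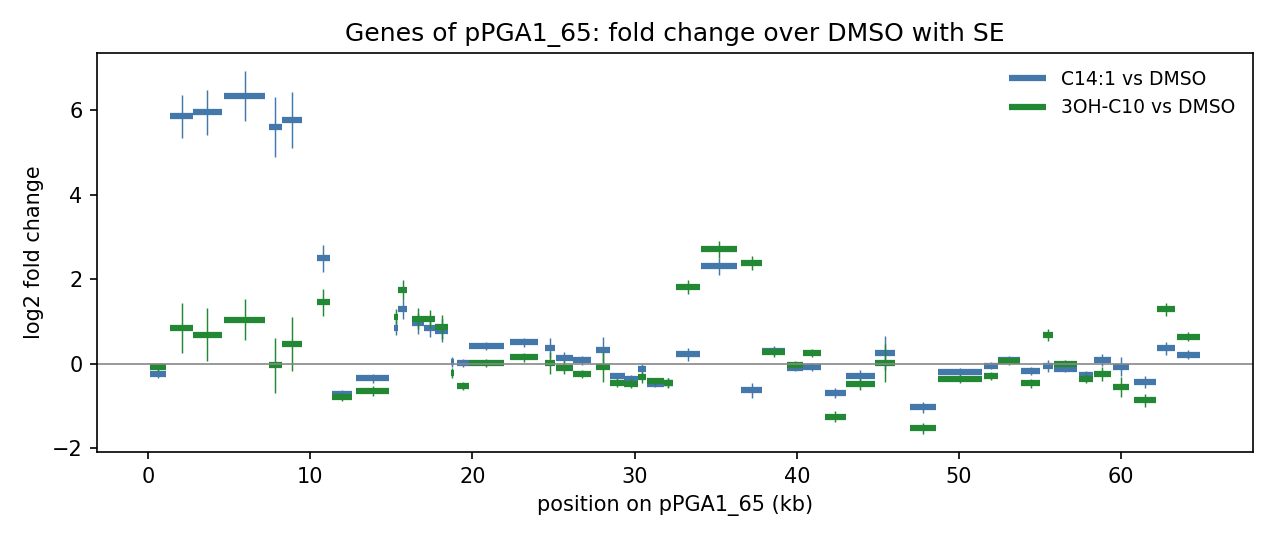
Log2 fold change over DMSO of the tested genes of pPGA1_65 along the plasmid for C14:1 and 3OH-C10, n = 3 libraries per group. Bars span each gene and vertical lines give the standard error. PGA1_65p00020 to PGA1_65p00060 (1376–9465) had a median of 5.86 with C14:1.

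With C14:1 hppD (2.11 ± 0.21, adjusted p = 4.5e-08, 208 against 48.2 CPM), rocF (1.94 ± 0.14, adjusted p = 1.18e-10, 56.1 against 14.7 CPM), hutG (1.80 ± 0.19, adjusted p = 4.51e-08, 33.5 against 9.63 CPM) and hutU (1.71 ± 0.14, adjusted p = 1.29e-09, 68.6 against 20.9 CPM) rose. The gene puuE beside uraH (1.65 ± 0.14, adjusted p = 1.61e-09, 268 against 85.7 CPM), comD (1.20 ± 0.23, adjusted p = 0.000141, 27.1 against 11.9 CPM), comE (1.13 ± 0.26, adjusted p = 0.000937, 10.7 against 4.94 CPM) and the xanthine dehydrogenase gene xdhB (1.25 ± 0.12, adjusted p = 3.14e-08, 207 against 87.1 CPM) rose. The nitrite reductase gene nirK (-2.72 ± 0.43, adjusted p = 3.55e-05, 20 against 131 CPM), ccrA (-2.69 ± 0.19, adjusted p = 1.81e-10, 118 against 758 CPM), groL (-2.68 ± 0.15, adjusted p = 2.74e-12, 774 against 4960 CPM), rpsE (-2.20 ± 0.17, adjusted p = 6.09e-10, 243 against 1120 CPM) and rplJ (-2.18 ± 0.20, adjusted p = 8.55e-09, 567 against 2570 CPM) fell. In energy metabolism nuoN (-1.65 ± 0.11, adjusted p = 7.48e-11, 342 against 1070 CPM) and the citrate synthase gene gltA (-1.36 ± 0.10, adjusted p = 2.7e-10, 211 against 543 CPM) fell. The run from PGA1_c12620 fell with C14:1 too (6 genes, median log2 fold change -5.57, median 20 against 971 CPM), with PGA1_c12640 at -6.48 ± 0.30, adjusted p = 9.57e-13, 22.5 against 2010 CPM. The run from PGA1_c13630 (21 genes) rose over DMSO with C14:1 (median log2 fold change 1.70, 528 against 129 CPM) but lay below untreated cells (1320 CPM). On pPGA1_262, 8 genes ending at PGA1_262p01230 (129188–135901, beside nirK) fell with C14:1 (8 genes, median log2 fold change -4.27, median 7 against 138 CPM).

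Of 50 ribosomal protein genes 0 rose, 42 fell and 8 did not pass (0 and 42 adjusted over the list alone, median log2 fold change -0.95). For ribosomal protein genes camera gave adjusted p = 1.21e-10, and adjusted p = 0.38 with an estimated correlation. Among 22 ATP synthase and respiratory genes 1 rose, 15 fell and 6 did not pass (1 and 15 adjusted over the list alone, median log2 fold change -0.77). Respiratory genes had a camera adjusted p = 4.16e-06, and adjusted p = 0.38 with an estimated correlation. Of 10 phenylacetate genes 7 rose, 0 fell and 3 did not pass (7 and 0 adjusted over the list alone, median log2 fold change 0.56), for example paaC (0.86 ± 0.09, adjusted p = 5.58e-08). By camera, phenylacetate genes had adjusted p = 0.00529, and adjusted p = 0.38 with an estimated correlation. Among 12 flagellar genes 2 rose, 0 fell and 10 did not pass (0 and 0 adjusted over the list alone, median log2 fold change 0.13 (0.06 under total counts)). Camera gave flagellar genes adjusted p = 0.496. These calls covered 3 of 15 lists, and 0 held with an estimated correlation, where 1 had an unadjusted p under 0.05 and fry called 9. Over untreated cells, neither ribosomal protein genes (median -0.16, camera adjusted p = 0.125) nor phenylacetate genes (0.24, adjusted p = 0.125) were called. Flagellar genes were (-0.93, adjusted p = 4.77e-06, and adjusted p = 0.583 with an estimated correlation). C14:1 changed 2143 genes, 971 higher and 1172 lower (213 and 224 at least 2-fold), and 65.3% of genes were separated against 10% by chance.

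Set against DMSO, C18:1 changed the fewest genes of the 3 AHLs. With untreated cells as control it changed the most (2029, against 1811 for 3OH-C10 and 1555 for C14:1), and by library names it was the only AHL in the lane of DMSO. Genes for ribosomal proteins rose, among them rplM (1.54 ± 0.24, adjusted p = 3.44e-05, 505 against 174 CPM), rplO (0.89 ± 0.12, adjusted p = 6.61e-06, 77.3 against 41.6 CPM) and rpmB (0.84 ± 0.13, adjusted p = 2.86e-05, 141 against 78.2 CPM). As with the other AHLs, rocF (2.41 ± 0.14, adjusted p = 1.32e-11, 77.7 against 14.7 CPM), ctlX (1.84 ± 0.12, adjusted p = 1.55e-10, 106 against 29.7 CPM), ocd (1.77 ± 0.14, adjusted p = 6.1e-09, 138 against 40.3 CPM) and hisD PGA1_c07750 (2.21 ± 0.24, adjusted p = 7.28e-07, 54.3 against 11.9 CPM) rose. The spermidine synthesis genes speD (1.72 ± 0.25, adjusted p = 1.86e-05, 48.6 against 14.6 CPM) and speE (1.52 ± 0.26, adjusted p = 8.45e-05, 15.8 against 5.35 CPM) and the chaperone gene dnaK (1.42 ± 0.19, adjusted p = 4.95e-06, 3150 against 1180 CPM) rose. The largest falls were in the adjacent genes PGA1_c26130 (-4.37 ± 0.36, adjusted p = 4.42e-08, 4.54 against 93.8 CPM) and PGA1_c26140 (-4.35 ± 0.24, adjusted p = 1.32e-11, 105 against 2140 CPM). Falls in genes with a symbol were moderate: ilvC (-1.46 ± 0.15, adjusted p = 1.73e-07, 138 against 380 CPM), groL (-1.34 ± 0.14, adjusted p = 2.56e-07, 1960 against 4960 CPM), mtoX, for methanethiol oxidase (-1.31 ± 0.12, adjusted p = 5.88e-08, 94.2 against 233 CPM), nuoN (-1.17 ± 0.11, adjusted p = 7.51e-08, 477 against 1070 CPM) and cobD, of cobalamin synthesis (-0.86 ± 0.10, adjusted p = 9.5e-07, 330 against 599 CPM). With untreated cells as control ilvC (-0.12, adjusted p = 0.522) and groL (-0.03, adjusted p = 0.881) did not pass.

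Other rises with C18:1 were hppD (1.29 ± 0.21, adjusted p = 5.25e-05, 118 against 48.2 CPM), the purine synthesis gene purC (1.05 ± 0.10, adjusted p = 1.71e-07, 142 against 68.5 CPM) and sdhD of succinate dehydrogenase (0.93 ± 0.12, adjusted p = 3.42e-06, 76.3 against 40 CPM). Neither flgN (0.12 ± 0.18, adjusted p = 0.644, 929 against 858 CPM) nor glnA (0.54 ± 0.38, adjusted p = 0.277, 2040 against 1400 CPM) passed. With only the 2 groups in the fit glnA did (0.48, adjusted p = 0.0386). With untreated cells as control both passed, glnA at 1.26 (adjusted p = 0.0103) and flgN at -1.14 (adjusted p = 1.83e-05). Of 50 ribosomal protein genes 26 rose, 2 fell and 22 did not pass (27 and 2 adjusted over the list alone, median log2 fold change 0.45), the only one of 15 lists called. For ribosomal protein genes camera gave adjusted p = 0.000215, and adjusted p = 0.934 with an estimated correlation. With an estimated correlation 0 were called and 0 had an unadjusted p under 0.05, while fry called 7. Among 12 flagellar genes 0 rose, 0 fell and 12 did not pass (0 and 0 adjusted over the list alone, median log2 fold change 0.1). Flagellar genes had a camera adjusted p = 0.738. Over untreated cells the ribosomal median was 1.19, and flagellar genes were called (-0.90, adjusted p = 2.27e-06, and adjusted p = 0.697 with an estimated correlation). C18:1 changed 1550 genes, 854 higher and 696 lower (115 and 30 at least 2-fold), or 709 and 835 with DESeq2 size factors, with 52.9% of genes separated against 10% by chance.

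Set against each other at the same dose, 3OH-C10 exceeded C14:1 in recA, flagellar genes and an 18-gene run without symbols. Differences were recA 2.94 ± 0.21, adjusted p = 2.3e-10, 5140 against 668 CPM, radC 2.62 ± 0.21, adjusted p = 1.72e-09, 623 against 101 CPM and flgN 2.18 ± 0.19, adjusted p = 3.19e-09, 3990 against 881 CPM. Further ones were flgC 2.17 ± 0.21, adjusted p = 2.15e-08, 1210 against 270 CPM, ctrA 1.74 ± 0.15, adjusted p = 2.5e-09, 17700 against 5280 CPM and PGA1_c24050 4.45 ± 0.18, adjusted p = 3.5e-14, 3100 against 142 CPM. The run PGA1_c17700 to PGA1_c17870 was also higher with 3OH-C10 (18 genes, median log2 fold change 3.19, median 57.5 against 6.37 CPM), while PGA1_c13630 to PGA1_c13830 was lower (21 genes, median log2 fold change -2.56, median 57.4 against 528 CPM). Lower with 3OH-C10 were PGA1_65p00050 (-5.64 ± 0.71, adjusted p = 3.61e-06, 28.9 against 1450 CPM), rpoH (-2.40 ± 0.57, adjusted p = 0.0026, 945 against 4990 CPM), hisD PGA1_c07750 (-1.39 ± 0.22, adjusted p = 2.75e-05, 41.5 against 109 CPM), lptG (-1.41 ± 0.15, adjusted p = 1.01e-07, 54.7 against 146 CPM) and rplP (-1.29 ± 0.17, adjusted p = 1.11e-06, 27.7 against 68.4 CPM). For glnA (log2 difference -0.32, 95% interval -1.14 to 0.50), groL (-0.15, -0.44 to 0.13), gltB (0.24, -0.16 to 0.63) and nuoN (0.10, -0.13 to 0.33) no difference between the 2 AHLs was detected.

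Of 12 flagellar genes 12 rose, 0 fell and 0 did not pass (12 and 0 adjusted over the list alone, median log2 fold change 1.68) for 3OH-C10 over C14:1. By camera, flagellar genes had adjusted p = 1.32e-16, and adjusted p = 0.156 with an estimated correlation. Among 50 ribosomal protein genes 1 rose, 37 fell and 12 did not pass (3 and 39 adjusted over the list alone, median log2 fold change -0.8). Camera gave ribosomal protein genes adjusted p = 7.36e-09, and adjusted p = 0.611 with an estimated correlation. Of 9 cell-cycle genes 6 rose, 1 fell and 2 did not pass (6 and 2 adjusted over the list alone, median log2 fold change 0.51 (0.01 under total counts)). For cell-cycle genes camera gave adjusted p = 0.0214, and adjusted p = 0.193 with an estimated correlation. Among 240 genes of pPGA1_262 81 rose, 17 fell and 142 did not pass (81 and 17 adjusted over the list alone, median log2 fold change 0.22 (-0.27 under total counts)). pPGA1_262 genes had a camera adjusted p = 0.00892, and adjusted p = 0.611 with an estimated correlation. With an estimated correlation 0 of 15 lists were called, 2 had an unadjusted p under 0.05 and fry called 7. The 2 AHLs differed in 1584 genes, 825 higher and 759 lower with 3OH-C10, or 721 and 939 with DESeq2 size factors, with 58.3% separated against 10% by chance. Under total counts 320 were higher and 2462 lower, with an all-gene median of -0.488 in place of -0.002.

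C18:1 stood above C14:1 in glnA (4.05 ± 0.43, adjusted p = 4.04e-07, 2040 against 123 CPM), nirK (3.64 ± 0.44, adjusted p = 2.39e-06, 249 against 20 CPM), gltB (3.24 ± 0.21, adjusted p = 7.72e-11, 1490 against 157 CPM) and rplM (2.57 ± 0.25, adjusted p = 4.89e-08, 505 against 85.1 CPM). Likewise higher were rpsF (2.35 ± 0.17, adjusted p = 8.24e-10, 330 against 64.5 CPM) and PGA1_c12640 (5.85 ± 0.29, adjusted p = 6.3e-12, 1300 against 22.5 CPM). It stood below C14:1 in PGA1_65p00020 (-5.49 ± 0.49, adjusted p = 7.17e-08, 6.93 against 311 CPM), rpoH (-2.63 ± 0.58, adjusted p = 0.00096, 807 against 4990 CPM), cpaB (-1.26 ± 0.18, adjusted p = 5.17e-06, 680 against 1630 CPM), hutU (-1.16 ± 0.13, adjusted p = 3.31e-07, 30.7 against 68.6 CPM) and paaC (-0.80 ± 0.09, adjusted p = 2.47e-07, 106 against 184 CPM). No difference was detected for flgN (log2 difference 0.08, 95% interval -0.29 to 0.45), motA (-0.08, -0.41 to 0.24) or PGA1_c26140 (0.18, -0.27 to 0.62). Of 50 ribosomal protein genes 49 rose, 0 fell and 1 did not pass (49 and 0 adjusted over the list alone, median log2 fold change 1.58). By camera, ribosomal protein genes had adjusted p = 2.16e-27, and adjusted p = 0.178 with an estimated correlation. Among 22 ATP synthase and respiratory genes 18 rose, 0 fell and 4 did not pass (19 and 0 adjusted over the list alone, median log2 fold change 0.78). Camera gave respiratory genes adjusted p = 1.82e-06, and adjusted p = 0.199 with an estimated correlation. Of 10 phenylacetate genes 0 rose, 10 fell and 0 did not pass (0 and 10 adjusted over the list alone, median log2 fold change -0.58). For phenylacetate genes camera gave adjusted p = 0.000127, and adjusted p = 0.199 with an estimated correlation. Among 15 chaperone and protease genes 9 rose, 0 fell and 6 did not pass (12 and 0 adjusted over the list alone, median log2 fold change 0.5). Chaperone and protease genes had a camera adjusted p = 0.00712, and adjusted p = 0.482 with an estimated correlation. Of 6 sulfur oxidation genes 0 rose, 5 fell and 1 did not pass (0 and 5 adjusted over the list alone, median log2 fold change -0.32). By camera, sulfur oxidation genes had adjusted p = 0.0393, and adjusted p = 0.395 with an estimated correlation. With an estimated correlation 0 of 15 lists were called, 3 had an unadjusted p under 0.05 and fry called 8. In all 1997 genes differed, 1156 higher and 841 lower with C18:1, or 974 and 1082 with DESeq2 size factors, and 65.6% were separated against 10% by chance.

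Relative to 3OH-C10, C18:1 gave higher glnA (4.37 ± 0.44, adjusted p = 5.97e-08, 2040 against 98.5 CPM), rpsF (3.16 ± 0.18, adjusted p = 1.27e-11, 330 against 36.8 CPM), rpsE (3.10 ± 0.18, adjusted p = 1.27e-11, 1130 against 132 CPM), gltB (3.01 ± 0.21, adjusted p = 8.34e-11, 1490 against 185 CPM) and ndk (2.98 ± 0.19, adjusted p = 4.33e-11, 237 against 29.8 CPM). Lower with C18:1 were radC (-2.44 ± 0.21, adjusted p = 2.16e-09, 115 against 623 CPM), recA (-2.35 ± 0.20, adjusted p = 1.99e-09, 1010 against 5140 CPM), hppD (-2.18 ± 0.21, adjusted p = 9.71e-09, 118 against 533 CPM), flgN (-2.10 ± 0.19, adjusted p = 2.35e-09, 929 against 3990 CPM) and PGA1_c24050 (-3.96 ± 0.18, adjusted p = 2.65e-13, 199 against 3100 CPM). No difference was detected for PGA1_65p00040 (log2 difference -0.07, 95% interval -1.07 to 0.93), rpoH (-0.23, -1.38 to 0.92) or cpaB (-0.35, -0.72 to 0.02). Among 50 ribosomal protein genes 49 rose, 1 fell and 0 did not pass (49 and 1 adjusted over the list alone, median log2 fold change 2.29). Camera gave ribosomal protein genes adjusted p = 3.66e-32, and adjusted p = 0.112 with an estimated correlation. Of 12 flagellar genes 0 rose, 12 fell and 0 did not pass (0 and 12 adjusted over the list alone, median log2 fold change -1.72). For flagellar genes camera gave adjusted p = 2.58e-10, and adjusted p = 0.304 with an estimated correlation. Among 10 phenylacetate genes 0 rose, 9 fell and 1 did not pass (0 and 9 adjusted over the list alone, median log2 fold change -0.82 (-0.26 under total counts)). Phenylacetate genes had a camera adjusted p = 0.00121, and adjusted p = 0.359 with an estimated correlation. Of 22 ATP synthase and respiratory genes 15 rose, 1 fell and 6 did not pass (15 and 1 adjusted over the list alone, median log2 fold change 0.74). By camera, respiratory genes had adjusted p = 0.00121, and adjusted p = 0.359 with an estimated correlation. Among 240 genes of pPGA1_262 41 rose, 114 fell and 85 did not pass (41 and 114 adjusted over the list alone, median log2 fold change -0.27 (0.28 under total counts)). Camera gave pPGA1_262 genes adjusted p = 0.00204, and adjusted p = 0.359 with an estimated correlation. With an estimated correlation 0 of 15 lists were called, 2 had an unadjusted p under 0.05 and fry called 9. The 2 AHLs differed in 2605 genes, 1304 higher and 1301 lower with C18:1, or 1264 and 1344 with DESeq2 size factors, with 74.4% separated against 10% by chance. Without 3OH-C10 replicate A, B or C the split was 1192 and 1210, 1199 and 1241, or 1239 and 1285. Total counts gave 2338 higher and 391 lower, with an all-gene median of 0.525 in place of -0.031.

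TDA changed 3136 genes, the most of the substances compared with DMSO, and lowered every flagellar gene tested. The flagellar chaperone gene flgN fell (-4.50 ± 0.21, adjusted p = 4.63e-15, 37.8 against 858 CPM), with fliF, of the basal-body ring (-3.43 ± 0.17, adjusted p = 1.76e-14, 236 against 2540 CPM), flaF (-3.29 ± 0.20, adjusted p = 4.61e-13, 134 against 1310 CPM) and flhA (-3.14 ± 0.16, adjusted p = 1.75e-14, 143 against 1270 CPM). Their regulators ctrA (-3.06 ± 0.15, adjusted p = 1.85e-14, 772 against 6440 CPM) and sciP (-3.66 ± 0.19, adjusted p = 2.69e-14, 43.3 against 550 CPM) fell as well. The Entner-Doudoroff genes for glucose breakdown fell, namely zwf PGA1_c27990 (-3.72 ± 0.20, adjusted p = 1.13e-13, 31.8 against 418 CPM), edd (-3.70 ± 0.24, adjusted p = 5.31e-12, 33.6 against 435 CPM) and eda (-3.49 ± 0.23, adjusted p = 5.04e-12, 8.11 against 91.1 CPM), while a glyceraldehyde-3-phosphate dehydrogenase gene, gap PGA1_c17250 (chromosome 1801467–1802468), rose (6.36 ± 0.18, adjusted p = 2.05e-18, 381 against 4.59 CPM). The largest rise of all was PGA1_c19730 (chromosome 2048268–2048438; 9.54 ± 0.32, adjusted p = 3.34e-17, 9680 against 13 CPM).

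Succinate dehydrogenase genes rose with TDA, namely sdhD (3.37 ± 0.13, adjusted p = 1.45e-16, 412 against 40 CPM), sdhC (2.96 ± 0.17, adjusted p = 1.01e-13, 879 against 113 CPM) and sdhA (2.34 ± 0.11, adjusted p = 5.49e-15, 1740 against 343 CPM), and so did the fumarase gene fumC (2.60 ± 0.13, adjusted p = 2.88e-14, 726 against 120 CPM). Rises were also found in queF and queD, of queuosine synthesis (3.82 ± 0.21, adjusted p = 6.14e-14, 127 against 8.88 CPM and 3.26 ± 0.28, adjusted p = 1.68e-10, 21.3 against 2.16 CPM) and in purB and purL, of purine synthesis (3.63 ± 0.20, adjusted p = 1.3e-13, 618 against 50 CPM and 2.74 ± 0.13, adjusted p = 7.96e-15, 623 against 93.2 CPM). Other rises were ccrA (3.50 ± 0.20, adjusted p = 1.44e-13, 8590 against 758 CPM), speE (3.34 ± 0.24, adjusted p = 1.96e-11, 56.2 against 5.35 CPM) and phnF (3.48 ± 0.16, adjusted p = 5.49e-15, 68.4 against 6.19 CPM). The DNA repair genes recN (1.54 ± 0.10, adjusted p = 1.11e-12, 726 against 249 CPM) and recO (1.39 ± 0.11, adjusted p = 7.17e-11, 115 against 44 CPM) and the chaperone gene dnaK (2.14 ± 0.19, adjusted p = 5.76e-10, 5180 against 1180 CPM) rose. Ribosomal protein genes that rose included rplO (2.88 ± 0.13, adjusted p = 1.76e-15, 306 against 41.6 CPM) and rpsD (3.02 ± 0.16, adjusted p = 4.18e-14, 282 against 34.4 CPM). Falls included radC (-3.54 ± 0.22, adjusted p = 2.14e-12, 16.7 against 195 CPM), preA (-3.56 ± 0.23, adjusted p = 9.62e-13, 80.4 against 947 CPM) and nirK (-3.42 ± 0.45, adjusted p = 1.14e-06, 12.3 against 131 CPM). Lower too were dprA (-2.64 ± 0.36, adjusted p = 1e-06, 1280 against 8000 CPM) and mtoX (-2.63 ± 0.13, adjusted p = 8.66e-15, 37.5 against 233 CPM). The genes of TDA biosynthesis carried no symbol and were not analysed here as a list.

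Of 12 flagellar genes 0 rose, 12 fell and 0 did not pass (0 and 12 adjusted over the list alone, median log2 fold change -2.77). For flagellar genes camera gave adjusted p = 4.06e-07, and adjusted p = 0.618 with an estimated correlation. Among 50 ribosomal protein genes 36 rose, 3 fell and 11 did not pass (36 and 3 adjusted over the list alone, median log2 fold change 0.91). Ribosomal protein genes had a camera adjusted p = 0.00589, and adjusted p = 0.705 with an estimated correlation. Of 240 genes of pPGA1_262 62 rose, 131 fell and 47 did not pass (62 and 131 adjusted over the list alone, median log2 fold change -0.46), with PGA1_262p01570 at -3.19 ± 0.09, adjusted p = 1.69e-18. By camera, pPGA1_262 genes had adjusted p = 0.0493, and adjusted p = 0.705 with an estimated correlation. Over untreated cells, medians were -3.83 for flagellar and 1.53 for ribosomal protein genes. The 3 of 15 lists were called by camera, and 0 were called with an estimated correlation, where 0 had an unadjusted p under 0.05 and fry called 13. Of the changed genes 1510 were higher and 1626 lower, 843 and 914 of them at least 2-fold, and 86% of genes were separated against 10% by chance. Total counts gave 1659 higher and 1445 lower and moved the all-gene median from -0.046 to 0.107.

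Over untreated cells, DMSP raised genes of its own breakdown, of ribosomal proteins and of the respiratory chain, and lowered flagellar genes. Both dmdD copies on pPGA1_262, whose products act late in DMSP demethylation, rose: dmdD PGA1_262p01850 (pPGA1_262 204271–205077; 7.24 ± 0.21, adjusted p = 2.77e-18, 1580 against 10.4 CPM) and dmdD PGA1_262p01540 (pPGA1_262 169466–170272; 5.21 ± 0.10, adjusted p = 7.12e-22, 1790 against 48.3 CPM). Their neighbour PGA1_262p01860 rose alike (7.25 ± 0.16, adjusted p = 1.58e-20, 1870 against 12.2 CPM), and the acryloyl-CoA reductase gene acuI rose (2.96 ± 0.15, adjusted p = 2.93e-14, 488 against 62.6 CPM). The DMSP lyase gene dddP did not pass (-0.21 ± 0.13, adjusted p = 0.154, 10.2 against 11.7 CPM), though it did without untreated replicate A (-0.33, adjusted p = 0.0352). Methylenetetrahydrofolate reductase metF fell most (-5.53 ± 0.32, adjusted p = 3.88e-13, 30.9 against 1420 CPM), although untreated libraries varied (30.9 ± 3.94 against 1420 ± 691 CPM (mean ± SD)).

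Spermidine synthesis genes speD (5.13 ± 0.27, adjusted p = 1.97e-13, 414 against 11.8 CPM) and speE (4.95 ± 0.25, adjusted p = 5.18e-14, 131 against 4.21 CPM), gap PGA1_c17250 (4.83 ± 0.18, adjusted p = 2.01e-16, 126 against 4.42 CPM) and the isoprenoid gene idi (4.16 ± 0.18, adjusted p = 1.37e-15, 121 against 6.75 CPM) rose with DMSP. So did rplM (4.95 ± 0.27, adjusted p = 2.64e-13, 3360 against 109 CPM), rpsL (4.17 ± 0.26, adjusted p = 2.6e-12, 2870 against 160 CPM) and the translational GTPase gene typA (4.08 ± 0.16, adjusted p = 7.33e-16, 494 against 29.3 CPM). In energy metabolism atpA (3.36 ± 0.19, adjusted p = 1.23e-13, 2190 against 214 CPM), petA of the cytochrome bc1 complex (3.59 ± 0.18, adjusted p = 3.32e-14, 1960 against 163 CPM) and the malate dehydrogenase gene mdh (3.35 ± 0.14, adjusted p = 1.15e-15, 1500 against 147 CPM) rose. The genes glnA (2.27 ± 0.40, adjusted p = 2.93e-05, 4090 against 849 CPM) and gltB (1.69 ± 0.20, adjusted p = 2.84e-08, 3110 against 962 CPM) rose as well. Untreated libraries differed widely for glnA (4090 ± 507 against 849 ± 640 CPM (mean ± SD)), and without untreated replicate A it was 2.93 (adjusted p = 7.33e-07). Falls included radC (-3.72 ± 0.22, adjusted p = 8.81e-13, 25.3 against 336 CPM), preA (-3.40 ± 0.22, adjusted p = 1.74e-12, 436 against 4590 CPM), ald (-3.05 ± 0.24, adjusted p = 7.67e-11, 96.6 against 799 CPM), dprA (-2.90 ± 0.37, adjusted p = 2.65e-07, 3330 against 24900 CPM) and hydA (-2.75 ± 0.16, adjusted p = 1.71e-13, 341 against 2300 CPM). Without untreated replicate C, dprA was -2.26 (adjusted p = 2.78e-07). Also lower were lexA, the SOS repressor gene (-2.36 ± 0.14, adjusted p = 1.9e-13, 200 against 1020 CPM), flgN (-2.49 ± 0.19, adjusted p = 2.38e-11, 364 against 2040 CPM) and ctrA (-1.84 ± 0.15, adjusted p = 5.39e-11, 3370 against 12100 CPM).

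Among 6 DMSP catabolism genes 5 rose, 0 fell and 1 did not pass (5 and 0 adjusted over the list alone, median log2 fold change 2.52), a call that held. Camera gave DMSP catabolism genes adjusted p = 8.91e-06, and adjusted p = 0.0159 with an estimated correlation. Of 50 ribosomal protein genes 49 rose, 0 fell and 1 did not pass (49 and 0 adjusted over the list alone, median log2 fold change 2.68). For ribosomal protein genes camera gave adjusted p = 2.64e-16, and adjusted p = 0.371 with an estimated correlation. Among 22 ATP synthase and respiratory genes 20 rose, 0 fell and 2 did not pass (20 and 0 adjusted over the list alone, median log2 fold change 1.12). Respiratory genes had a camera adjusted p = 0.000147, and adjusted p = 0.371 with an estimated correlation. Of 10 phenylacetate genes 0 rose, 10 fell and 0 did not pass (0 and 10 adjusted over the list alone, median log2 fold change -1.2), for example paaC (-1.54 ± 0.09, adjusted p = 4.77e-13). By camera, phenylacetate genes had adjusted p = 0.00688, and adjusted p = 0.409 with an estimated correlation. Among 12 flagellar genes 0 rose, 12 fell and 0 did not pass (0 and 12 adjusted over the list alone, median log2 fold change -1.68). Camera gave flagellar genes adjusted p = 0.00096, and adjusted p = 0.451 with an estimated correlation. Of 240 genes of pPGA1_262 46 rose, 145 fell and 49 did not pass (46 and 145 adjusted over the list alone, median log2 fold change -0.62). For pPGA1_262 genes camera gave adjusted p = 0.00645, and adjusted p = 0.417 with an estimated correlation. Among 63 genes of pPGA1_78 16 rose, 41 fell and 6 did not pass (16 and 41 adjusted over the list alone, median log2 fold change -0.78). pPGA1_78 genes had a camera adjusted p = 0.0033, and adjusted p = 0.371 with an estimated correlation. Camera called these 7 of 15 lists, and 1 with an estimated correlation. With DMSO as control, flagellar genes (median -0.76, camera adjusted p = 0.12) and pPGA1_262 genes (-0.46, adjusted p = 0.0526) were not called, and the ribosomal median was 1.97. DMSP changed 3229 genes, 1540 higher and 1689 lower (979 and 1000 at least 2-fold), with 83.5% separated against 10% by chance. Total counts gave 1681 higher and 1466 lower and moved the all-gene median from -0.127 to 0.068.

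**Figure D4:**
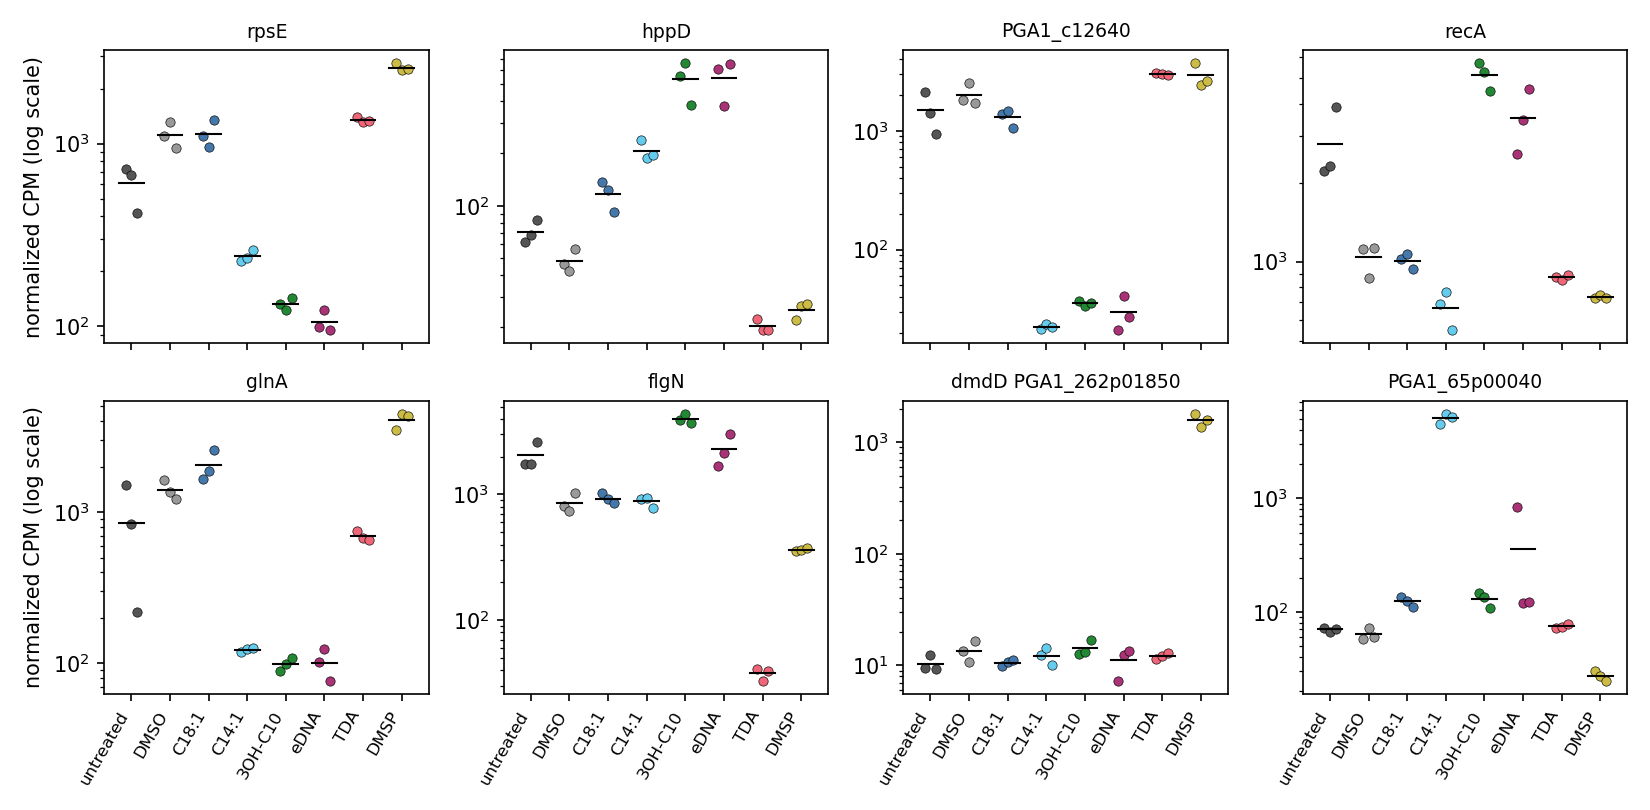
Normalized CPM of 8 genes in each of the 24 libraries, on a log scale. Each point is 1 library and the bar is the mean of 3. Examples are dmdD PGA1_262p01850 with DMSP (1580 against 10.4 CPM), PGA1_65p00040 with C14:1 (5090 against 63.3 CPM) and flgN with TDA (37.8 against 858 CPM).

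Extracellular DNA raised hutI and rocF and lowered glnA, gltB and ribosomal protein genes, and the competence gene dprA did not pass against untreated cells. The histidine utilization genes hutI (3.13 ± 0.21, adjusted p = 7.33e-11, 122 against 14 CPM) and hutH (2.80 ± 0.17, adjusted p = 1.07e-11, 190 against 27.2 CPM) rose, with rocF (2.96 ± 0.13, adjusted p = 1.49e-13, 159 against 20.4 CPM), hppD (2.94 ± 0.21, adjusted p = 2.42e-10, 545 against 70.7 CPM) and ctlX (2.36 ± 0.12, adjusted p = 1.12e-12, 177 against 34.5 CPM). Thioredoxin trxC (2.54 ± 0.16, adjusted p = 1.24e-11, 176 against 30.1 CPM), thioredoxin reductase trxB (1.68 ± 0.20, adjusted p = 4.25e-07, 110 against 34.4 CPM) and the peptidoglycan precursor gene dapF (2.25 ± 0.25, adjusted p = 1.53e-07, 99.4 against 21.1 CPM) rose. Falls in genes with a symbol were led by glnA (-3.07 ± 0.42, adjusted p = 3.33e-06, 101 against 849 CPM), rpmD (-3.00 ± 0.25, adjusted p = 1.82e-09, 7.87 against 63.3 CPM), rplQ (-2.85 ± 0.20, adjusted p = 1.14e-10, 34.7 against 250 CPM), rpsE (-2.52 ± 0.17, adjusted p = 6.49e-11, 105 against 607 CPM) and gltB (-2.42 ± 0.20, adjusted p = 9.08e-10, 180 against 962 CPM). Without untreated replicate A glnA was -2.38 (adjusted p = 8.05e-06). The competence gene dprA (-0.57 ± 0.34, adjusted p = 0.157, 16800 against 24900 CPM) did not pass, nor did comD (0.20 ± 0.24, adjusted p = 0.479, 16.1 against 14 CPM) and comE (0.49 ± 0.27, adjusted p = 0.121, 8.38 against 5.96 CPM). With DMSO as control comE (0.77, adjusted p = 0.0175) and dprA (1.07, adjusted p = 0.0094) rose. For dprA, untreated libraries differed widely (16800 ± 2930 against 24900 ± 16300 CPM (mean ± SD)), and the log2 fold change was -0.89 (adjusted p = 0.0218) without untreated replicate A and 0.09 (adjusted p = 0.794) without replicate C.

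Further falls with eDNA were ccrA (-2.37 ± 0.19, adjusted p = 5.98e-10, 130 against 671 CPM), ilvC (-2.16 ± 0.16, adjusted p = 1.33e-10, 33.6 against 150 CPM) and atpD (-2.12 ± 0.16, adjusted p = 1.45e-10, 123 against 536 CPM). The genes nuoL (-1.62 ± 0.12, adjusted p = 2.42e-10, 284 against 873 CPM), ntrX, a nitrogen regulator gene (-1.26 ± 0.09, adjusted p = 1.06e-10, 194 against 464 CPM), and mtoX (-1.38 ± 0.12, adjusted p = 2.15e-09, 83.7 against 218 CPM) fell too. Rises included dnaK (1.77 ± 0.19, adjusted p = 5.35e-08, 3370 against 991 CPM), lpxC, of lipid A synthesis (1.69 ± 0.18, adjusted p = 3.07e-08, 1590 against 492 CPM), pstC (1.79 ± 0.29, adjusted p = 2.5e-05, 70.8 against 20.5 CPM) and sciP (1.17 ± 0.17, adjusted p = 3.13e-06, 1740 against 771 CPM). The rise of rpoH (1.96 ± 0.56, adjusted p = 0.00579, 3320 against 851 CPM) rested on replicate A, without which its log2 fold change was 0.59 (adjusted p = 0.182). Among genes without symbols PGA1_c04490 rose (3.82 ± 0.21, adjusted p = 3.74e-12, 566 against 39.9 CPM). The run PGA1_c12620 to PGA1_c12670 fell (6 genes, median log2 fold change -5.06, median 21.7 against 664 CPM), with PGA1_c12640 at -5.65 ± 0.29, adjusted p = 1.61e-12, 29.6 against 1500 CPM. PGA1_c13630 to PGA1_c13830 also fell with eDNA (21 genes, median log2 fold change -4.77, median 46.6 against 1.32e+03 CPM). Of the genes for nucleoside use, deoD fell (-0.52 ± 0.12, adjusted p = 0.000436, 168 against 241 CPM). PGA1_65p00020 to PGA1_65p00060 had a median log2 fold change of 2.13 that rested on replicate A, where PGA1_65p00040 stood at 841 CPM against 120 and 122 in replicates B and C.

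Of 50 ribosomal protein genes 6 rose, 33 fell and 11 did not pass (6 and 33 adjusted over the list alone, median log2 fold change -0.83). By camera, ribosomal protein genes had adjusted p = 0.000121, and adjusted p = 0.734 with an estimated correlation. Among 22 ATP synthase and respiratory genes 4 rose, 13 fell and 5 did not pass (4 and 13 adjusted over the list alone, median log2 fold change -0.67). Camera gave respiratory genes adjusted p = 0.0127, and adjusted p = 0.734 with an estimated correlation. Of 8 oxidative stress genes 6 rose, 1 fell and 1 did not pass (7 and 1 adjusted over the list alone, median log2 fold change 0.75). For oxidative stress genes camera gave adjusted p = 0.0171, and adjusted p = 0.723 with an estimated correlation. Among 23 genes for the SOS response and DNA repair 7 rose, 9 fell and 7 did not pass (7 and 9 adjusted over the list alone, median log2 fold change -0.15), such as ruvB (-0.84 ± 0.09, adjusted p = 3.07e-08). SOS and repair genes had a camera adjusted p = 0.644. Over DMSO the ribosomal median was -1.56, and flagellar genes were called (0.94, adjusted p = 0.000913, and adjusted p = 0.592 with an estimated correlation). Called lists were 3 of 15, and 0 with an estimated correlation, where 1 had an unadjusted p under 0.05 and fry called 11. With eDNA 2373 genes changed, 1212 higher and 1161 lower (305 and 330 at least 2-fold), and 53.6% were separated against 10% by chance. The fit of the 2 groups alone gave 1624 genes. The balance turned without untreated replicate A (1146 higher, 1151 lower), untreated replicate B (1082 and 1111) or eDNA replicate A (1151 and 1155).

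Responses to substances over DMSO overlapped to different degrees. In a fit of those 15 libraries, 3OH-C10 and C14:1 moved 1965 genes the same way (946 higher, 1019 lower) and 115 in opposite ways, where independent lists would share 882. C18:1 shared 1105 genes with 3OH-C10 (393 opposite, 701 for independent lists) and 1094 with C14:1 (273 opposite, 597 for independent lists). TDA shared 1257 genes with C18:1 (425 opposite, 806 for independent lists), 1043 with 3OH-C10 (1376 opposite, 1190 for independent lists) and 943 with C14:1 (1132 opposite, 1020 for independent lists). Among the genes moved alike by 3OH-C10 and C14:1 were glnA (-3.83 ± 0.43 and -3.51 ± 0.42), rocF (3.54 ± 0.14 and 1.94 ± 0.14) and PGA1_c12640 (-5.83 ± 0.29 and -6.48 ± 0.30). Simulated unchanged groups over 3 simulated DMSO libraries shared at most 1 called gene. With no gene changed few are called, so this cannot size the real overlaps. Fold changes correlated at 0.49 to 0.52 there, so part of any correlation comes from the shared control. The observed correlation was 0.71 for 3OH-C10 and C14:1, 0.35 for 3OH-C10 and C18:1, 0.41 for C14:1 and C18:1, and 0.33 for C18:1 and TDA. The covariances of these pairs were 0.514, 0.157, 0.148 and 0.245, against 0.011 in the simulations. For TDA the correlation was -0.10 with 3OH-C10 (covariance -0.151) and 0.01 with C14:1 (covariance 0.014). By library names, 3OH-C10, C14:1 and TDA were in lane 4 and DMSO in lane 3, so the 3 would share a lane difference.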

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

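All tests of explanations in this part were chosen after the result was seen. Ribosomal protein genes differed between AHLs given at the same dose, by a test of the difference itself. Their median log2 fold change was 1.58 for C18:1 over C14:1 and 2.29 for C18:1 over 3OH-C10, and 49 genes were higher in each. These differences do not involve a control, but with untreated cells in place of DMSO the medians were -0.98 for 3OH-C10, -0.16 for C14:1 and 1.19 for C18:1, where DMSO itself had a median of 0.73 over untreated cells. Examples are rpsE (2.22 ± 0.17, adjusted p = 1.28e-09 over C14:1 and 3.10 ± 0.18, adjusted p = 1.27e-11 over 3OH-C10), rpsF (2.35 ± 0.17, adjusted p = 8.24e-10 over C14:1) and rplM (2.57 ± 0.25, adjusted p = 4.89e-08 over C14:1), with n = 3 per group. The camera calls for these lists did not hold with an estimated correlation (adjusted p = 0.178 and adjusted p = 0.112).

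Genes of ribosomal proteins went opposite ways with C18:1 and with C14:1 and 3OH-C10 when each was set against DMSO. An error of scaling would move all genes alike, but under total counts the ribosomal median differed from that of all other genes by 1.57 for C18:1 over C14:1, 2.33 for C18:1 over 3OH-C10, -0.95 for C14:1 over DMSO and -1.76 for 3OH-C10 over DMSO, with quartiles apart, which argues against normalization for these parts. For C18:1 over DMSO the difference was 0.41 and the quartiles overlapped (0.21 to 0.84, and -0.22 to 0.33 for all other genes), so normalization stays open for that rise. By library names C18:1 and DMSO were in lane 3 and C14:1, 3OH-C10 and TDA in lane 4, and TDA had a median of 0.91 over DMSO, but with no control in lane 4 the lane cannot be told apart from the substance. Within lane 4, 3OH-C10 lay below C14:1 with a median of -0.80, and a difference between the AHLs themselves stays open as an untested hypothesis, which the 3 AHLs and DMSO sequenced in 1 lane would test.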

How the results depend on the processing

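Total-count scaling, the other control for lists, the alternatives for overlap and runs were chosen after the data were seen. Other settings were planned. Across 66 recounts of changed genes, 64 stayed within 1.5 times the reported count. With only the 2 groups in the fit, DMSO against untreated gave 1120 genes in place of 1697, and with total-count scaling 3OH-C10 against C14:1 gave 2782 in place of 1584. The cause was not tested. With only the 2 groups in the fit the balance turned for C18:1 (795 higher, 840 lower), TDA (1663 and 1604), eDNA (798 and 826), 3OH-C10 against C14:1 (887 and 1004) and C18:1 against C14:1 (1090 and 1133). For 3OH-C10 it turned with untreated cells as control (985 and 826). Leaving out 1 library gave 1252 to 1762 genes for DMSO against untreated, 2448 to 2639 for 3OH-C10, 1859 to 2075 for C14:1, 1196 to 1379 for C18:1 and 3042 to 3081 for TDA. The ranges were 3138 to 3215 for DMSP, 2193 to 2349 for eDNA, 1238 to 1513 for 3OH-C10 against C14:1, 1681 to 1932 for C18:1 against C14:1, and 2373 to 2524 for C18:1 against 3OH-C10. With the other control, 1811 genes were called for 3OH-C10, 1555 for C14:1, 2029 for C18:1, 3209 for TDA, 3140 for DMSP and 2738 for eDNA. Of the reported genes 1645, 1015, 967, 2836, 2882 and 1985 were called again in that order.

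Gene lists depended on the correlation assumed. Lists called by camera went with an estimated correlation from 4 to 0 for DMSO against untreated, 5 to 0 for 3OH-C10, 3 to 0 for C14:1, 1 to 0 for C18:1, 3 to 0 for TDA, 7 to 1 for DMSP and 3 to 0 for eDNA. With the other control 5, 3, 2, 5, 5 and 6 lists were called for 3OH-C10, C14:1, C18:1, TDA, DMSP and eDNA. With an estimated correlation they went from 4 to 0 for 3OH-C10 against C14:1, 5 to 0 for C18:1 against C14:1 and 5 to 0 for C18:1 against 3OH-C10. The lists with unadjusted p under 0.05 numbered 1, 1, 1, 0, 0, 2, 1, 2, 3 and 2 in the order of all 10 comparisons, and fry called 8, 12, 9, 7, 13, 14, 11, 7, 8 and 9.

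Pairing by letter (A to C) was not seen but stays open. Correlations over 0.1 held in 16 of 84 same-letter and 41 of 168 other pairs. Of 24 libraries, 6 were closest to their own letter. With a replicate block 1650, 2628, 2091, 1493, 3123, 3218 and 2326 genes were called for DMSO, 3OH-C10, C14:1, C18:1, TDA, DMSP and eDNA. Between AHLs the block gave 1533, 1952 and 2579, and called lists kept their number in all 10 comparisons.

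For 223 named gene results, 2830 of 2844 checks kept direction and call, 5 lost the call, 5 gained it and 4 changed sign. With untreated cells as control flgN was -1.14 for C18:1. With DMSO as control dprA was 1.07 and comE 0.77 with eDNA, and dddP was 0.057 with DMSP. For eDNA, dprA was -0.889 without untreated replicate A and 0.094 without replicate C.

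All 30 rechecks of the overlap between substances stayed within 1.5 times the reported counts. The 6 libraries of a comparison split in 10 ways, the real one included, too few for a share under 0.05, and 1 split in each, the real one, gave as many genes. The highest of the others was 193 for eDNA (real 2373), 1 for DMSO against untreated (real 1697), 1 for 3OH-C10 against DMSO (real 2647) and 0 for the other 7 comparisons (real 1550 to 3229). An alternative without ribosomal and transfer RNA genes was not run, as these were not counted.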

Other observations

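The tests of explanations and eDNA overlaps below were chosen after the result was seen. The lists were chosen after the symbols were read and before any count was tested. With DMSP, of 13 purine synthesis genes 13 rose, 0 fell and 0 did not pass (13 and 0 adjusted over the list alone, median log2 fold change 2.71). For purine synthesis genes camera gave adjusted p = 5.08e-08, and adjusted p = 0.129 with an estimated correlation. With TDA 12 rose, 0 fell and 1 did not pass (12 and 1 adjusted over the list alone, median log2 fold change 2.08). Purine synthesis genes had a camera adjusted p = 2.83e-05, and adjusted p = 0.142 with an estimated correlation. With C18:1 9 rose, 0 fell and 4 did not pass (9 and 0 adjusted over the list alone, median log2 fold change 0.81). By camera, purine synthesis genes had adjusted p = 8.42e-05, and adjusted p = 0.199 with an estimated correlation. Of 18 aminoacyl-tRNA synthetase genes 18 rose, 0 fell and 0 did not pass (18 and 0 adjusted over the list alone, median log2 fold change 2.19) with DMSP. Camera gave synthetase genes adjusted p = 4.97e-09, and adjusted p = 0.129 with an estimated correlation. With 3OH-C10 1 rose and 13 fell (camera adjusted p = 0.0192, and adjusted p = 0.558 with an estimated correlation). Over untreated cells the median was -0.16 (camera adjusted p = 0.513). Among 14 TCA cycle genes 11 rose, 2 fell and 1 did not pass (11 and 2 adjusted over the list alone, median log2 fold change 1.84) with TDA. For TCA cycle genes camera gave adjusted p = 0.000238, and adjusted p = 0.166 with an estimated correlation. Of 17 genes for histidine synthesis and use 9 rose, 3 fell and 5 did not pass (9 and 4 adjusted over the list alone, median log2 fold change 0.49) with C14:1. Histidine genes had a camera adjusted p = 0.00368, and adjusted p = 0.0371 with an estimated correlation. With eDNA 10 rose, 2 fell and 5 did not pass (10 and 2 adjusted over the list alone, median log2 fold change 0.55). By camera, histidine genes had adjusted p = 0.0165, and adjusted p = 0.0407 with an estimated correlation. With DMSO as control the list was not called for eDNA (adjusted p = 0.0719). Among 17 genes for aromatic amino acid and hydroxyphenylacetate catabolism, 13 rose, 0 fell and 4 did not pass (13 and 0 adjusted over the list alone, median log2 fold change 0.64) with C14:1. Camera gave aromatic catabolism genes adjusted p = 0.000373, and adjusted p = 0.201 with an estimated correlation. With DMSP 0 rose, 13 fell and 4 did not pass (0 and 13 adjusted over the list alone, median log2 fold change -1.21), where hpaR fell (-2.02 ± 0.09, adjusted p = 5.81e-15). For aromatic catabolism genes camera gave adjusted p = 0.00356, and adjusted p = 0.201 with an estimated correlation. Of 17 cobalamin synthesis genes 1 rose, 12 fell and 4 did not pass (1 and 12 adjusted over the list alone, median log2 fold change -0.97) with C14:1. Cobalamin synthesis genes had a camera adjusted p = 0.000449, and adjusted p = 0.158 with an estimated correlation. With 3OH-C10 4 rose and 10 fell (camera adjusted p = 0.031, and adjusted p = 0.305 with an estimated correlation). DMSO itself raised 10 and lowered 0 over untreated cells (camera adjusted p = 0.0069, and adjusted p = 0.454 with an estimated correlation). Over untreated cells medians were -0.22 for C14:1 and -0.15 for 3OH-C10 (camera adjusted p = 0.143 and adjusted p = 0.447).

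The response to eDNA resembled those to the AHLs although no library is shared. By library names eDNA, 3OH-C10, C14:1 and TDA were in lane 4 and both controls and C18:1 in lane 3. Those in lane 4 would share a lane difference. eDNA moved 1455 genes the same way as 3OH-C10 and 268 the opposite way, where independent lists would give 812 and 813. The counts were 1183 and 265 with C14:1 (657 and 659 for independent lists), 1127 and 86 with C18:1 (477 and 475) and 1390 and 587 with TDA (962 and 963), with correlations across genes of 0.59, 0.44, 0.52 and 0.26. Shared members include rocF (2.96 ± 0.13 with eDNA, 3.54 ± 0.14 with 3OH-C10) and glnA (-3.07 ± 0.42 and -3.83 ± 0.43).

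The run of genes on pPGA1_262 beside nirK (129188–135901) was lower with 3OH-C10, C14:1, TDA and eDNA, with medians of -3.88, -4.27, -4.33 and -2.68. With eDNA the replicates varied, and PGA1_262p01170 stood at 24.6, 208 and 35.7 CPM in A, B and C. Under total counts the run's median lay below that of all other genes, by -2.72 where nearest. The run was picked for 2-fold changes, so this gap was built in and does not test normalization. By library names all 4 groups were in lane 4, within which 3OH-C10 and C14:1 differed by 0.29. Lane and treatment cannot be told apart here.

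PGA1_65p00020 to PGA1_65p00060 were higher with C14:1 and in eDNA replicate A. The run was lower with 3OH-C10 than with C14:1 (median -5.28), both in lane 4, which argues against the lane. The other genes of pPGA1_65 had a median of -0.01 with C14:1, which argues against the copy number of the plasmid. Reads of a C14:1 library in eDNA replicate A would raise other genes high with C14:1 alike, but 11 such genes did not follow: with the level in eDNA replicates B and C subtracted, their median in replicate A was -0.524% of the C14:1 level, against 13.1 to 20.6% for the 5 genes of the run. A response to C14:1 may explain the first part, as a hypothesis that new cultures with and without C14:1 would test, and for eDNA replicate A no biological explanation was tested.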
